A study of Mycobacterium avium with 6 samples.

How the data were processed

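RNA of Mycobacterium avium MAC101 was measured in 6 libraries, 2 with an antibiotic and 4 controls. Per the labels' protocols, bacteria were lysed by bead beating, ribosomal RNA was depleted, and a directional paired-end library was made with the dUTP method and sequenced on an Illumina platform. The groups and replicate numbers were read from the sample titles. The aligner, the counter, their versions and the strand setting are not given in the sources used here. The genome is M_avium_101 v1.0, per the file headers and columns, with features between positions 1 and 5482218. Of the feature lengths, 96.8% are multiples of 3, so most are coding lengths. No reference annotation was used.

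The authors deposited whole-number counts per feature and library, per the file headers, and these counts were the input of every test. They also deposited RPKM values, which were used only to derive the total behind each library, and TPM values, which sum to 1000000 in each library. The columns the authors named CPM do not sum to 1000000 and were treated as a scaled signal, since the deposited values equal the counts divided by 1 effective size per library. The authors' deposited comparison table holds a log2 fold change, a signed fold change (a score, with falls written as negative reciprocals), p-values and adjusted p-values, and the larger group mean. How the authors tested is not given in the sources used here. Of its 5229 features, 45 had no value. Its log2 fold changes correlated with those computed here at r = 1.000 across 5107 genes, which are not independent replicates.

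Features were kept by edgeR's filterByExpr and scaled by TMM, and tested with edgeR 4.0.16 (glmQLFit with robust dispersion, glmQLFTest) under R 4.3.3, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05, two-sided. Normalised counts are TMM-scaled counts per 1000000 (CPM), and log2 values per library use a prior count of 2. The common biological coefficient of variation was 0.463. A standard error is the log2 fold change divided by the square root of F. Of 50 gene lists fixed beforehand, matched by symbol since the files pair no product names, 12 matched no feature, 8 had fewer than 4 members tested and 30 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. Symbols with a copy number at the end were matched without it. The rule for named genes, fixed before the data were examined, took up to 12 genes per direction with an adjusted p under 0.05, a mean of at least 20 counts and no overlap between groups; up to 3 passing members of each passing list; and 19 drug-response genes whatever their result. Genes named outside it were chosen after their values were seen and are marked as such.

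Libraries of each group were checked for duplicates: the chi-square per degree of freedom of counts lay between 7.51 and 216 for pairs within a group, so no pair agreed within sampling noise. The groups share no replicate number. The count floor of a library is the 5th percentile of counts per kilobase over features of at least 300 bp; subtracting it times the feature length before the fit was an added alternative. Library sets (controls 1 and 4 with antibiotic 6, controls 7 and 10 with antibiotic 11) were defined after the data were seen. Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter and at least 50 counts in 2 libraries. Further ones fixed then left out the structural RNA features rnpB, ssrA, ffs and rrf (matched by name only), used pairs of controls, or left out each library. Non-robust dispersion and the authors' table were also fixed then. A pseudocount alternative was meant only for tables without counts and did not apply.

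The test was tried on simulated data for the 5107 tested genes of the antibiotic over control comparison, with 200 genes changed, in 5 simulations. Counts were drawn independently from the control means and the real dispersions and library sizes, without differences between library sets or in count floor. With 200 changed genes the adjusted p threshold is easier to pass than in data with 4 genes called. The shares called may therefore be too high for these libraries. Of the genes changed 2-fold, 4.40% were called, with 52.6% at 4-fold, 81.9% at 8-fold and 94.4% at 16-fold. Of unchanged genes 0.164% were called. Figures were drawn with matplotlib 3.10.9.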

Results

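The transcriptome of Mycobacterium avium strain MAC101, an opportunistic lung pathogen that grows slowly in broth, was measured by RNA sequencing with and without exposure to an antibiotic. The series text names the compound only by a code, JNJ8464; the sample titles carry a different code, and the labels do not say whether it is the same compound. The comparison asked which transcripts differed after 1.5 h with 10 µM of the compound in cultures brought to late log phase at 28.5 °C. There were 2 antibiotic libraries (replicates 6 and 11) and 4 control libraries (replicates 1, 4, 7 and 10), and nothing in the labels says whether these came from independent cultures, so p-values measure the spread between these samples. The protocol names control 4 under both solvents used for controls, DMSO and PBS, and does not name control 7, so the 4 controls were taken as 1 group.

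The count table held 5229 features of the genome M_avium_101 v1.0, of which 779 had a gene symbol and 4450 only a locus identifier. Total counts lay between 5259306 (antibiotic 11) and 7123115 (antibiotic 6), with 5344675 to 6145384 in the controls. rnpB, the RNA of ribonuclease P, and ssrA, the transfer-messenger RNA that rescues stalled ribosomes, together took 46.1% to 51.1% of the counts in 5 libraries and 19.2% in antibiotic 11. The level that 5% of features of at least 300 bp fell below was 217 counts per kilobase in antibiotic 11 and 103 in control 10, against 23.2 to 33.5 in the other 4 libraries. The libraries of 1 group also differed from each other: Spearman's correlation across genes was 0.735 between both antibiotic libraries. Between controls it ranged from 0.825 (controls 4 and 10) to 0.984 (controls 1 and 4). Control 10 and antibiotic 11 correlated at 0.898, and antibiotic 6 correlated with control 4 at 0.966.

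**Figure D1:**
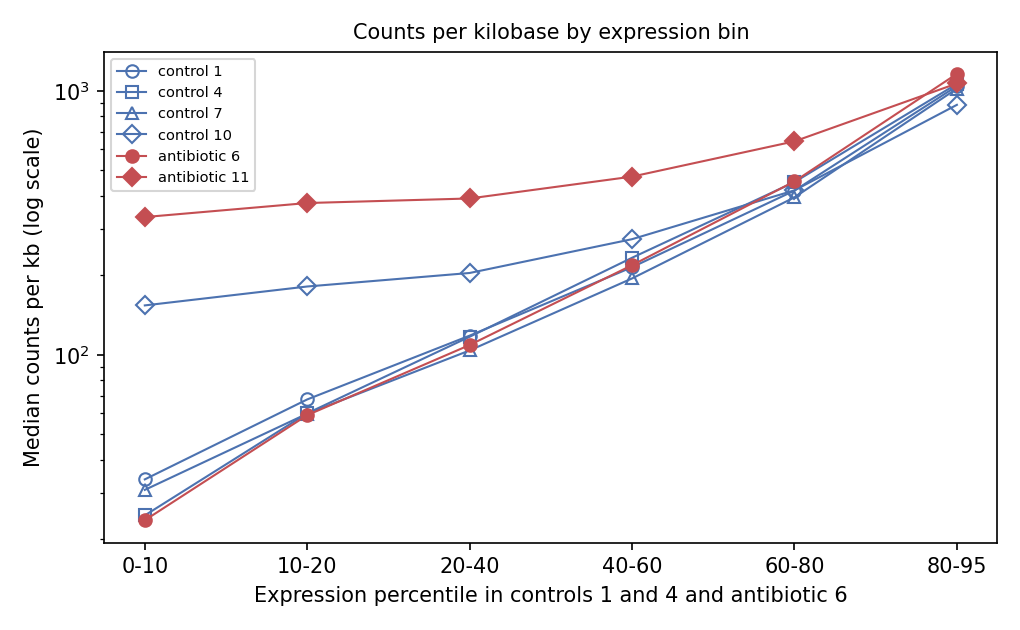
Median counts per kilobase (log scale) of features grouped by their expression percentile in controls 1 and 4 and antibiotic 6, with a line for each of the 6 libraries. In the lowest group antibiotic 11 reached 332 and control 10 reached 154 counts per kilobase, while the other libraries lay between 23.6 and 33.7.

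With the antibiotic, lat, which encodes the L-lysine aminotransferase of lysine breakdown (2061987 to 2063327, plus strand), rose 7.33-fold. Its normalised count, in TMM-scaled counts per 1000000 (CPM), was 431 ± 99.3 (SD, n = 2) with the antibiotic and 58.8 ± 12.1 (SD, n = 4) in the controls. ACR0Q2_04510 (858900 to 859589, plus strand) rose 42.0-fold, from 13.4 ± 6.58 (SD, n = 4) to 566 ± 211 CPM (SD, n = 2). ACR0Q2_07100 (1412928 to 1413368, minus strand) rose 15.6-fold, from 23.3 ± 4.31 (SD, n = 4) to 364 ± 174 CPM (SD, n = 2). The feature next to ACR0Q2_04510 on the opposite strand (859611 to 860021) rose 8.85-fold, from 6.22 ± 1.57 (SD, n = 4) to 55.4 ± 6.91 CPM (SD, n = 2). Its raw counts were low in controls 1, 4, 7 and 10, at 30, 23, 28 and 52. The files pair no product names with locus identifiers, and whether counting used strand is not given in the sources used here. Whether the feature next to ACR0Q2_04510 rose separately from ACR0Q2_04510 therefore cannot be told.

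These 4 genes were all that passed edgeR's quasi-likelihood test at an adjusted p under 0.05 among 5107 features tested, all 4 were higher, and 0 were lower. The log2 fold change of lat was 2.87 with a standard error of 0.35 (edgeR adjusted p = 0.0454). That of ACR0Q2_04510 was 5.39 with a standard error of 0.54, and that of ACR0Q2_07100 was 3.96 with a standard error of 0.37 (edgeR adjusted p = 0.0248 for both). For each of the 4 genes, both antibiotic libraries lay above all 4 controls. Such separation was no more frequent over all features than chance gives: 354 lay above and 328 below all controls, 13.4% in all against 13.3%. At an unadjusted p under 0.05 there were 234 features, 120 higher and 114 lower, and DESeq2 called 16 higher and 4 lower. Within 2 sets of libraries that were defined after the data were seen, the log2 difference of lat was 2.88 for antibiotic 6 over controls 1 and 4, and 2.87 for antibiotic 11 over controls 7 and 10. With the count floor subtracted these differences were 2.98 and 3.67. A term for these sets of libraries, added after the data were seen, gave 8 genes, all higher, with all 4 of the above among them. Leaving out control 1, 4 or 7 left 0 genes at the threshold (118, 174 and 120 at an unadjusted p under 0.05), leaving out antibiotic 6 left 1, and leaving out antibiotic 11 left 6. Without control 10 there were 4 genes, of which lat was not one (edgeR adjusted p = 0.0858), and lat did not pass with RLE factors (0.0658) or with limma-voom (0.132) either.

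**Figure D2:**
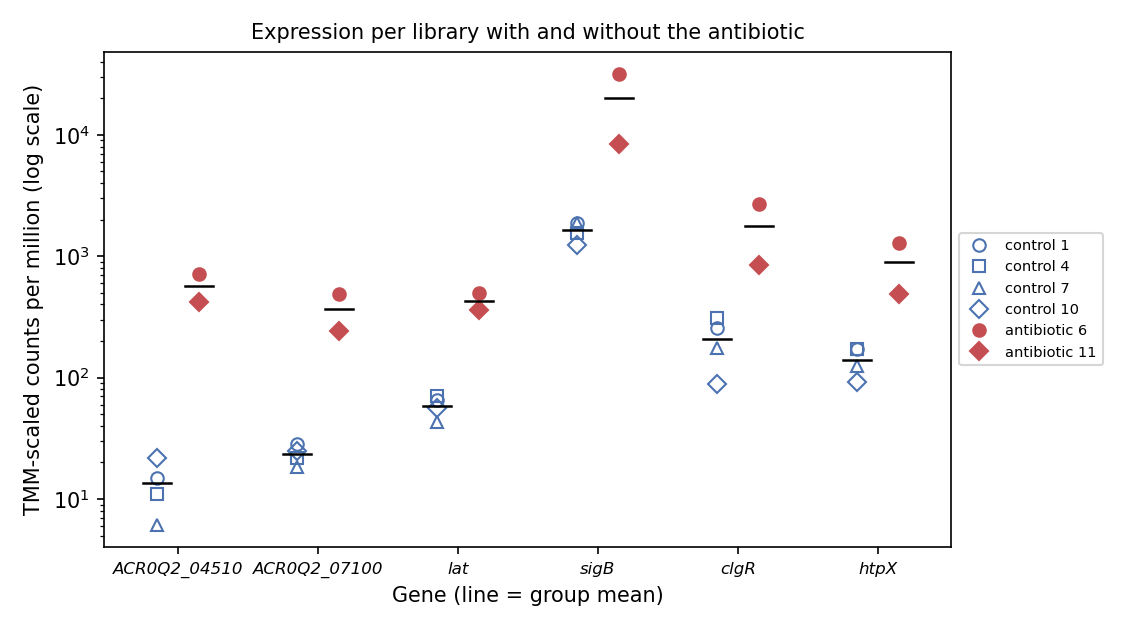
TMM-scaled CPM (log scale) of 6 genes in each library, with open symbols for the 4 controls, filled symbols for the 2 antibiotic libraries and a line at each group mean. For each gene both antibiotic libraries lie above all controls, with lat between 361 and 502 against 43.2 to 71.1. sigB, clgR and htpX passed in the authors' deposited table and not in the main edgeR test.

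The authors' deposited table called 13 genes at its own adjusted p under 0.05, 12 higher and 1 lower, including the 4 above. Those with a symbol were lat, sigB, clgR and htpX, of which the last 3 are named here after their values were seen. sigB encodes an alternative sigma factor of the mycobacterial stress response, and the authors' deposited table gave it a 12.2-fold rise. clgR encodes a transcriptional activator of Clp protease genes, with an 8.52-fold rise in the authors' deposited table. htpX encodes a membrane-bound metalloprotease, with a 6.33-fold rise in the authors' deposited table. The lower gene was ACR0Q2_01435 (259774 to 259992), at a log2 fold change of -2.20 in the authors' deposited table.

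In the present test sigB stood at 31654 and 8384 CPM in antibiotic 6 and 11, against 1635 ± 298 (SD, n = 4) in the controls. Its log2 fold change was 3.61 with a standard error of 0.66, which did not pass (edgeR adjusted p = 0.432). The log2 fold change of clgR was 3.09 with a standard error of 0.65 (edgeR adjusted p = 0.640), and that of htpX was 2.66 with a standard error of 0.50 (edgeR adjusted p = 0.496). Both antibiotic libraries lay above all controls for sigB, clgR and htpX, as they did for 354 features. Leaving out 1 library at a time gave 2.36 to 4.28 for sigB, 2.04 to 3.70 for clgR and 1.80 to 3.20 for htpX. Over 20 alternative fits sigB passed in 4, clgR in 3 and htpX in 4. With the library set term their log2 fold changes were 3.41, 2.98 and 2.56 and none passed (edgeR adjusted p = 0.125, 0.0590 and 0.0567). All 3 passed with DESeq2 (adjusted p = 1.40e-07, 0.000815 and 0.000196) and in 2 alternatives added after the data were seen. With that term and the count floor subtracted they were 3.57, 3.20 and 2.80 (edgeR adjusted p = 0.0318, 0.0109 and 0.00755). With control 10 and antibiotic 11 both left out, sigB (edgeR adjusted p = 0.0145), clgR and htpX (edgeR adjusted p = 0.0337 for each) were among 10 genes called.

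Of 52 ribosomal protein genes, 50 had a negative log2 fold change, with a median of -0.54 (camera with a preset correlation of 0.01, adjusted p = 1.47e-11). The correlation estimated between these genes was 0.876, so they moved largely together and are not independent. With that estimate the camera adjusted p = 0.959. Of the 52 members, 0 passed either over all genes or adjusted over the list alone. The fall lay in antibiotic 11, where the median was -1.58 against controls 7 and 10, while antibiotic 6 had a median of -0.03 against controls 1 and 4. For rpsL, a ribosomal protein gene named after its values were seen, those differences were -2.88 and -0.25. Antibiotic 11 is also the library with the fewest counts in rnpB and ssrA, the most counts per kilobase in its least expressed features, and 6.22% of its counts in 1 feature of 3113 bp, against 0.966% to 1.41% elsewhere. With the count floor subtracted, the median of antibiotic 11 was -1.45. At the preset correlation the list passed (camera adjusted p = 1.14e-09, and 5.74e-08 with the set term). Without antibiotic 11 the list's direction turned to higher and it did not pass (camera adjusted p = 0.371), nor did it with control 10 left out as well (0.645).

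The list of sigma factors and anti-sigma factors, which set promoter choice of RNA polymerase, passed as higher (camera with a preset correlation, adjusted p = 0.0337). Of its 6 members 5 were positive, with a median of 0.41 against 0.13 over all features tested. With an estimated correlation the adjusted p = 0.959. The largest log2 fold changes were 3.61 for sigB and 1.81 for sigE, the sigma factor of envelope stress. That of sigE had a standard error of 0.67 (edgeR adjusted p = 0.883). The list was not tested without sigB and sigE. 0 members passed over all genes and 1, sigB, passed adjusted over the list alone. sigC stood at -0.47, and sigI, sigM and rseA, the anti-sigma factor of sigE, stood at 0.14, 0.19 and 0.63; without antibiotic 11 sigI and sigM were negative. Within the sets the median was 0.47 for antibiotic 6 and 0.37 for antibiotic 11. Without control 10 the list did not pass (camera adjusted p = 0.112), nor did it without antibiotic 6 (0.251), with limma-voom (0.192) or with controls 1 and 7 alone (0.176).

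**Figure D3:**
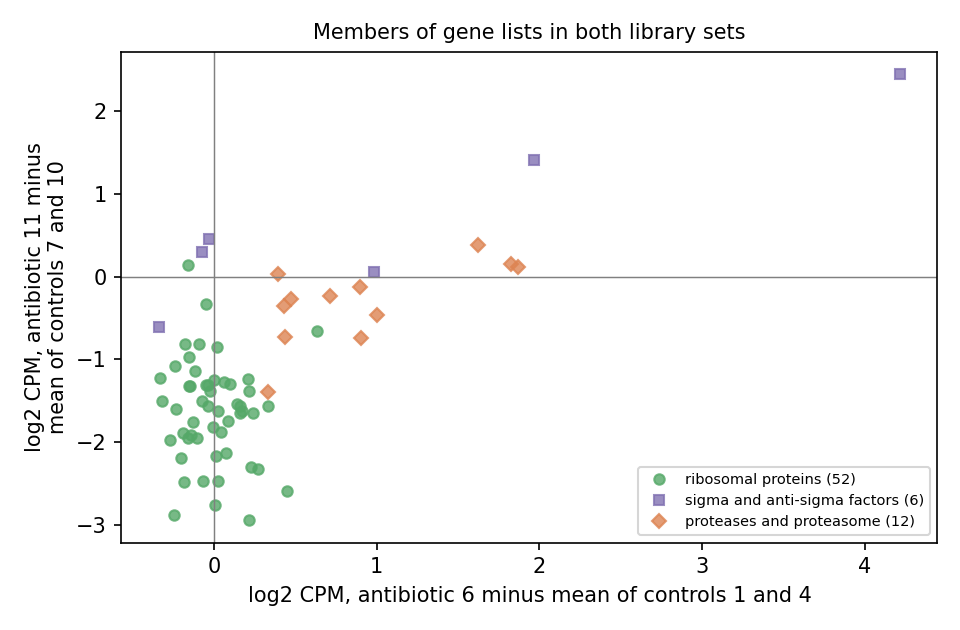
Log2 CPM of antibiotic 6 minus the mean of controls 1 and 4 (horizontal axis) and of antibiotic 11 minus the mean of controls 7 and 10 (vertical axis), with 1 point per gene of 3 lists. The 52 ribosomal protein genes lie around a median of -0.03 horizontally and -1.58 vertically, while sigB lies at 4.22 and 2.45.

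The remaining 28 of the 30 lists tested did not pass, and with an estimated correlation or with fry 0 of the 30 did. Genes of menaquinone, heme and isoprenoid synthesis had 11 of 13 members positive (camera adjusted p = 0.109). Their median was 0.32 in antibiotic 6 against controls 1 and 4 and 0.36 in antibiotic 11 against controls 7 and 10. Without control 4 they passed as higher (camera adjusted p = 0.0129). Among proteases and the proteasome, which degrade damaged and tagged proteins, 10 of 12 members were positive, with a median of 0.32 (camera adjusted p = 0.207) and 0 members past the threshold. Their median was 0.80 in antibiotic 6 against controls 1 and 4 and -0.25 in antibiotic 11 against controls 7 and 10. With the count floor subtracted these medians were 0.75 and 0.02. With the floor subtracted and the set term the proteases did not pass (camera adjusted p = 0.0587). They passed as higher without antibiotic 11 (camera adjusted p = 2.06e-06), without control 7 (0.0473), without control 10 and antibiotic 11 (2.78e-05), with controls 4 and 10 alone (0.0156) and with the count floor subtracted (0.0152). Without antibiotic 6 their direction was lower and they did not pass (0.334). Chaperones and heat shock genes had 6 of 11 members positive and a median of 0.16 (camera adjusted p = 0.820), with medians of 0.54 and -0.56 in the respective sets. They passed as lower without antibiotic 6 (camera adjusted p = 0.0411) and as higher without antibiotic 11 (9.93e-05). SOS response and DNA repair genes had a median of -0.02 and a mean of 0.02 over 19 members (camera downward, adjusted p = 0.951). Of mycolic acid genes, which build the waxy outer membrane, 5 were positive and 8 negative. Among them acpM, kasA and kasB_2, named after their values were seen, stood at 1.70, 1.74 and 1.52, and inhA at -0.82. Over 13 members the mycolic acid genes had a median of -0.32 and a mean of 0.07 (camera downward, adjusted p = 0.366). Their medians were 0.18 and -0.71 in the respective sets. They passed as lower without antibiotic 6 (camera adjusted p = 0.000703) and as higher without antibiotic 11 (0.00506). Of 6 genes of iron acquisition and storage, 5 were positive, and the negative member was a storage gene. The median of all 6 was 0.73 (camera adjusted p = 0.371), with medians of -0.02 and 1.23 in the respective sets. With the count floor subtracted the latter were 0.46 and 2.15.

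Of 19 drug-response and drug-target genes chosen before the data were examined, 10 were found by symbol, as 11 features, and 0 of the 11 passed edgeR's test, over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom). The DNA damage genes recA and lexA stood at log2 fold changes of -0.26 and -0.03, with standard errors of 0.59 and 0.54, and both were positive without antibiotic 11. dnaK, a heat shock chaperone, stood at 0.39 and the chaperonin genes groL_1 and groL_2 at -0.17 and -0.27, with standard errors between 0.61 and 0.80; dnaK was negative without antibiotic 6 and the chaperonin genes were positive without antibiotic 11. Among targets of known drugs, atpB of ATP synthase stood at -0.89, gyrA of DNA gyrase at -0.56 and inhA, the enoyl reductase of mycolic acid synthesis, at -0.82. embB, an arabinosyltransferase gene, stood at 0.24 and was negative without antibiotic 11. katG, which encodes catalase-peroxidase, stood at -0.77, and purF, of purine synthesis, stood at -0.17 and was positive without antibiotic 11. Leaving out 1 library at a time gave -1.15 to -0.58 for atpB, -0.94 to -0.26 for gyrA, -1.55 to -0.34 for inhA and -1.58 to -0.25 for katG. The edgeR adjusted p of these features lay between 0.883 and 0.992.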

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

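All tests of explanations in this part were chosen after the results they address were seen. Among 45 quantities checked over the 4 controls with Dixon's ratio of gap to range, 4 had a control far from the others, where chance alone gives about 1 in 20. The count floor had a ratio of 0.883, from control 10 at 103 counts per kilobase. The longest of the 5 most counted features (4963696 to 4966808) had a ratio of 0.953, from 1.41% of counts in control 7 against 0.966% to 0.988% in the other controls. purF had a ratio of 0.886, from 205 CPM in control 10 against 276 to 286 in the other controls. gyrA had a ratio of 0.834, from 833 CPM in control 7 against 472 to 532 in the other controls.

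The high count floor of control 10 and antibiotic 11 was compared with control 7 across expression groups, with control 7 scaled by 0.773 and 0.711, the ratios of medians in the 240 most expressed features. The excess over scaled control 7 was 130 counts per kilobase in the least expressed features and 115 in those between the 60th and 80th percentile in control 10, and 311 and 363 in antibiotic 11. The ratio farther from 1 was 1.17, which is consistent with reads spread evenly over the features. Low counts of rnpB and ssrA are not the source in control 10, since those genes took 47.5% of its counts, within the range of the other controls. Whether such reads could come from genomic DNA stays open: 77.4% of the reads of antibiotic 11 fell in features, the lowest of the 6 libraries, but the strand setting of the counting is not given in the sources used here, and no biological explanation was tested.

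Between controls 1 and 4 and controls 7 and 10, edgeR called 535 genes, whereas the other pairings of the controls (1 and 7 against 4 and 10, 1 and 10 against 4 and 7) gave 0 genes, with 14 and 172 at an unadjusted p under 0.05. Subtracting the count floor did not lower this number, with 609 genes called. In control 10 it took off 103 counts per kilobase, below an excess of 115 to 135 in features up to the 80th percentile. Part of the floor thus remained, so the floor is not excluded as a source. Separate sets of cultures or libraries may explain it, but the test did not decide: across genes, the difference of antibiotic 11 and antibiotic 6 correlated with control 7 minus controls 1 and 4 at 0.420. With control 10 in place of control 7 it was 0.813. For pairs of controls it was 0.731 for 7 and 10 minus 1 and 4, and 0.606 for 4 and 10 minus 1 and 7. For 4 and 7 minus 1 and 10 it was -0.713, where control 10 is on the subtracted side. The pair holding control 10 thus lay toward antibiotic 11 in every pairing, so the correlation did not single out this one. The vehicle of the controls cannot be told apart from this pairing of 535 genes, because the protocol names control 4 under both vehicles and control 7 under neither.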

How the results depend on the processing

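Alternatives other than the library set term, the count floor, both together, and leaving out control 10 with antibiotic 11 were set before the data were examined. All 4 called genes kept a positive log2 fold change under all 20 alternative fits: 2.62 to 3.34 for lat, 4.95 to 6.27 for ACR0Q2_04510, 3.37 to 4.42 for ACR0Q2_07100 and 3.01 to 4.37 for the feature next to ACR0Q2_04510. They passed in 10, 15, 16 and 11 of the 20, with adjusted p from 1.54e-12 to 1.000 for lat. The feature next to ACR0Q2_04510 did not pass, among others, with upper-quartile factors (0.138), limma-voom (0.0862) or structural RNAs left out (0.0550), and stood at 20.6-fold with floor and set term. The number of genes changed was 4 in the main test, and all of these 4 were among those called by DESeq2, with the set term, with the floor subtracted, with both, without control 10 and antibiotic 11, and in the authors' deposited table. No paired analysis was possible because the groups share no replicate number. With 1 antibiotic library left out, the other is assumed to vary as the controls do.

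DESeq2 called 20 genes (16 higher, 4 lower, 19 at least 2-fold). limma-voom called 2 genes, and so did edgeR with structural RNA features left out; in each case both were higher and at least 2-fold (2 and 2). With controls 4 and 10 alone 0 genes were changed, 0 higher and 0 at least 2-fold, with 20 at an unadjusted p under 0.05. The set term gave 8 genes (8 higher, 8 at least 2-fold). The floor with the set term gave 15 (14 higher, 1 lower, 15 at least 2-fold). Leaving out control 10 and antibiotic 11 gave 10 (10 higher, 10 at least 2-fold). The authors' deposited table gave 13. Leaving out 1 library at a time gave 0 to 6 genes changed, 0 to 6 higher and 0 to 6 at least 2-fold.

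The number of gene lists past the threshold, 2 in the main test, was 4 with upper-quartile factors, 1 with limma-voom, 1 with controls 1 and 7 alone, 0 with an estimated correlation and 4 without control 10 and antibiotic 11. Leaving out 1 library gave 1 to 9 lists: 9 without antibiotic 6 and 8 without antibiotic 11. The cause of these changes was not tested. Fits with fewer libraries also have fewer degrees of freedom.

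These named genes, none of which passed in the main test, changed sign. With limma-voom lexA stood at 0.010, and with controls 4 and 10 alone groL_1 stood at 0.0020 and sigM at -0.078. Without control 10 and antibiotic 11, purF stood at 0.16, embB at -0.23, groL_1 at 0.32, groL_2 at 0.22, recA at 0.23, lexA at 0.35 and sigI at -0.21. With 1 library left out at a time, log2 fold changes ranged from -1.74 to 0.57 for groL_1, -1.82 to 0.47 for groL_2, -1.01 to 0.55 for lexA and -1.46 to 0.40 for recA. They ranged from -0.78 to 0.27 for purF, -0.28 to 0.62 for embB, -0.81 to 1.04 for dnaK and -0.14 to 1.14 for rseA. They ranged from -0.21 to 0.42 for sigI and -0.23 to 0.52 for sigM. They ranged from -0.78 to 1.09 for htrA, -0.18 to 2.50 for acpM and -0.016 to 2.51 for kasA. Over all named genes and alternatives, 28 values changed sign, 28 lost the threshold, 16 gained it and 668 did neither. Depth was 5259306 to 7123115 counts per library, and the simulation called 4.40% of genes changed 2-fold, so smaller changes were mostly not detectable with these libraries.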

Other observations

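The tests in this part were chosen after the results were seen, and the genes were singled out by their values. Beside sigB, clgR and htpX, other genes of envelope stress were higher with the antibiotic, with both antibiotic libraries above all 4 controls, and did not pass edgeR's test on all 6 libraries. Separation of this kind is no evidence by itself, since 13.4% of all features had it in either direction, against 13.3% by chance. pspA and pspM, which follow clgR on the same strand (2689601 to 2691241) and belong to the membrane stress response, stood at log2 fold changes of 1.82 and 1.53. mprA, the response regulator of an envelope stress system, stood at 1.31 and sigE at 1.81. Leaving out 1 library at a time moved pspA from 0.54 to 2.49, pspM from 0.94 to 1.95, mprA from 0.78 to 1.70 and sigE from 0.66 to 2.45, with the lowest value of each without antibiotic 6. The neighbours of sigE did not stand apart: rseA and the protease gene htrA stood at 0.63 and 0.43. Of genes for Clp proteases, clpC1 stood at 1.10 and clpP2 at 1.18, and their differences were 1.62 and 1.83 in antibiotic 6 but 0.38 and 0.16 in antibiotic 11.

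amaB and hglS, whose names are those of lysine breakdown enzymes, lie next to lat on the opposite strand (2058667 to 2061452) and stood at 1.34 and 1.25 (edgeR adjusted p = 0.640 and 0.708). acpM, kasA and kasB_2, neighbouring fatty acid elongation genes of the mycolic acid list (4257022 to 4259957), stood at 1.70, 1.74 and 1.52. Their standard errors were 0.78, 0.81 and 0.68, and acpM and kasA were slightly negative without antibiotic 6. Of genes acting on the cell wall, ripC, a peptidoglycan hydrolase gene, stood at -1.81 and rpfC, a resuscitation-promoting factor gene, at -1.39, with ranges of -2.29 to -1.44 and -1.99 to -0.96 when 1 library was left out. With DESeq2 amaB, hglS and ripC passed (adjusted p = 0.0496 for each). With the count floor subtracted and a term for the library sets, amaB (edgeR adjusted p = 0.0318) and ripC (edgeR adjusted p = 0.0477) passed, as did sigB, clgR and htpX.

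A hypothesis is that exposure to the antibiotic raised an envelope stress response of sigB, sigE, clgR, pspA, pspM, htpX and mprA. Their median log2 fold change was 1.82, and 1.89 with the count floor subtracted, so the subtracted part of the floor does not account for it. In antibiotic 11 the subtraction took off 217 counts per kilobase, less than its excess of 311 to 363. With the floor subtracted and a term for the library sets, the lowest of the 7 was 1.55 (standard error 0.248), and sigB, clgR and htpX passed. Each set holds 2 controls and 1 antibiotic library, so a constant difference between the sets shifts both groups alike. The term could therefore hardly lower these values, and the fit does not decide whether the sets contribute. The vehicle stays open: the median was 1.92 against controls 4 and 10, but the protocol names control 4 under both vehicles. The genes were chosen because they were higher, so no test of the pattern itself was made.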
